A study of Mus musculus with 8 samples.

How the data were processed

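The samples were 8 RNA-seq libraries of total RNA from mouse skin at postnatal day 0.5, made from 2 sorted cell populations of 4 pups. Per the labels' protocols, cells positive for K14RFP (a red fluorescent reporter of keratin 14 expression) and high for alpha6 integrin were sorted, and high or low P-cadherin separated hair germ from interfollicular epidermis. RNA was extracted with Trizol and made into libraries with a SMARTer stranded total RNA kit for low input. Transgenic pups 4 and 6 carried pTRE2-200bcl, a miR-200 construct under a doxycycline-responsive promoter, together with K14rtTA, a transactivator under the keratin 14 promoter, and dams received doxycycline chow during pregnancy. Of the control pups, 3 carried K14rtTA and 5 carried pTRE2-200bcl, on a mixed strain background, so neither control had both parts of the system and the 2 controls differed in genotype.

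The deposited files hold 1 raw read count per gene symbol and library. Per the submitters' processing notes, the tools were TopHat, HTSeq and DESeq2 and the genome build was mm10 (GRCm38), while versions and the strand setting are not given in the sources used here. A feature named miR200primary was counted beside the annotated genes, and its coordinates are not given in the sources used here. The authors also deposited a matrix of normalised signal, in which the values equal the counts divided by 1 constant per library for the 23406 names found in both tables. That matrix was used only to read those constants and to check the counts, and 27 names did not match, most of them altered into dates in the matrix. The counts covered 23433 symbols plus 5 summary lines per library, which were left out of the tests. Of all reads recorded by HTSeq, 23.4% to 42.4% were assigned to genes, 30.0% to 47.8% lay outside genes, and 12.5% to 46.5% aligned to more than 1 place. Counts assigned to genes ranged from 7109871 to 14039583 per library. A gene with a count of 0 was given an upper limit of 3 counts, equal to 0.199 to 0.522 CPM (edgeR library-scaled counts) in single libraries, and such limits and all count intervals (95%) cover counting error only. Folds against a group with 0 counts in both libraries use a floor of 3 counts over the group. Folds and ratios divide summed counts by summed TMM-scaled library sizes, so they differ from ratios of mean CPM.

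Groups were the 4 combinations of population and genotype, each with 2 pups. The pup numbers recur in both populations, and per the labels each number is 1 animal, so hair germ and interfollicular epidermis libraries are paired by pup while the genotype arms share no pup. The pairing was checked as the correlation across genes of each pup's deviation from its group mean, which was 0.117 in controls and 0.0868 in transgenics over all tested genes and 0.394 and 0.191 over the 7365 genes with a mean log2 CPM of at least 4. Pups are biological replicates, and no library had technical repeats.

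Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Counts were scaled by TMM (trimmed mean of M values), filtered with filterByExpr by group to 14176 genes, and fitted as 4 group means over all 8 libraries with glmQLFit and its newer quasi-likelihood method (legacy set to FALSE, which is not the default of this version). Contrasts were tested with glmQLFTest, two-sided, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05 within each contrast. The common biological coefficient of variation was 0.4746, with 4 residual degrees of freedom and 7.821 prior degrees of freedom. The contrasts were transgenic against control in each population, hair germ against interfollicular epidermis in each genotype, and the difference of the transgenic effect between populations.

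The contrasts, the tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule took, among genes with an adjusted p under 0.05, a mean log2 CPM of at least 2 and no overlap between the libraries of the 2 arms, the 10 largest rises and 10 largest falls (5 and 5 for the difference of effects), leaving out predicted and clone-named genes. It added up to 3 members with the smallest p from each list in the transgenic contrasts, and in every contrast the sort genes Cdh3, Itga6 and Krt14, the miR-200 loci, Zeb1 and Zeb2. A further 2 genes are not reported here. Genes outside this rule are named as chosen after their values were seen.

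The 39 lists held 736 entries, of which 715 were found among the symbols. They covered miR-200 loci and textbook targets, skin identities, signalling pathways, junctions, adhesion, polarity, cell cycle, stress and housekeeping classes, and markers of other cell types. Lists with at least 3 tested members were tested with camera in limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2, adjusted over the 35 lists of a contrast), and again with an estimated correlation, with fry, and with the pup as a block for contrasts between populations. The estimated correlation was the more cautious setting and called 0 lists in all 5 contrasts. Not tested were the miR-200 loci, the mitochondrial transcripts (0 of 15 found), and the erythroid and adipocyte lists, with 0 and 2 tested members. A myeloid list of 257 genes and a list of 16 imprinted growth genes were added after the calls were seen.

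For seed sites, the longest annotated 3' UTR of each gene was taken from the GENCODE mouse annotation and its transcript sequences. UTRs were found for 13330 of the 14176 tested genes (94.0%), after matching 21783 symbols by name and 1277 by synonym, with 373 unmatched. Each was searched for CAGTATT, the match to bases 2 to 8 of miR-200b and miR-429, and for CAGTGTT, the match for miR-200a. The mean log2 fold change of genes with and without a site was compared by a two-sided permutation test with 100000 resamples (Python 3.11.15, numpy 2.4.6, pandas 2.3.3), and each word was ranked among the 419 other words with the same bases. Genes are not independent replicates, so these tests describe these libraries. Plots were drawn with matplotlib 3.10.9.

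The procedure was tested on simulated data with known changes at the same group sizes. With edgeR it recovered 59.7% of genes changed by 2 on the log2 scale in the hair germ contrast, 46.3% in interfollicular epidermis, 52.2% and 41.8% in the contrasts between populations in controls and transgenics, and 40.3% for the difference of effects, with 2 to 6 false calls per contrast. At a change of 1 the same shares were 14.9%, 11.9%, 13.4%, 11.9% and 2.99%. The simulated genes were drawn independently, with 1 mean per gene before the changes and the fitted trend of the dispersion. They held no pup effect, no spread of single genes around that trend and no difference in spread between populations. The shares and false calls therefore describe the simulation and may not hold for the real libraries.

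Alternatives tried were DESeq2 size factors, library size alone, no filter, a filter of 5 CPM in 2 libraries, the DESeq2 1.42.0 Wald test, the edgeR legacy method, limma-voom, a fit of the 4 libraries of a contrast, the pup as a fixed or random block, leaving out each library in turn, and leaving out before scaling either ribosomal RNA, Rn45s and the 10 most abundant genes or the lists of other cell types. Added after the data were seen were fits without the other cell type and myeloid lists, without the 2 libraries with over 20% Rn45s, without both transgenic interfollicular epidermis libraries, and without both libraries of pup 4. Raw reads, isoforms, introns and alignments were not analysed here.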

Results

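RNA was sequenced from hair germ and interfollicular epidermis of newborn mice that expressed a miR-200 transgene in keratin 14-positive cells, and from control pups of the same age. The series asks how this microRNA family bears on cell adhesion and polarity while hair follicles form. The hair germ is the early epithelial bud of the follicle, and the interfollicular epidermis (IFE) is the skin epithelium between follicles. There were 4 groups of 2 libraries, from control pups 3 and 5 and transgenic pups 4 and 6 in each population. Counts assigned to genes were 10327474 and 14039583 in hair germ controls, 10775495 and 7109871 in hair germ transgenics, 7393908 and 12253892 in IFE controls, and 9113851 and 11684585 in IFE transgenics. Values are given per group as TMM-scaled CPM with the SD over n = 2 pups, and log2 fold changes with their SE and an edgeR adjusted p. The edgeR test returns no SE, so the SE is the absolute log2 fold change over the square root of its F statistic. It is not the spread between the 2 pups of a group.

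Libraries differed in ways other than their group. Rn45s, the precursor of ribosomal RNA, took 30.6% of counts in IFE control pup 3 and 29.0% in IFE transgenic pup 4, against 3.56% to 13.01% in the other 6 libraries. Pup 4 was the only male by expression, with 2156 and 1535 counts of Y-linked genes and 44 and 62 of Xist, while the other libraries had 0 to 4 Y-linked counts and 18356 to 48347 of Xist. The first principal component held 34.9% of the variance and the next 19.1%. On the second, hair germ control pups 3 and 5 lay at 45.7 and -59.8. Over all tested genes these 2 libraries had a Pearson r of 0.872, against 0.882 to 0.932 with the IFE control libraries. The hair germ transgenic pair had 0.878, the IFE control pair 0.935 and the IFE transgenic pair 0.969. Over genes with a mean log2 CPM of at least 4 the hair germ pairs had 0.900 and 0.927.

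The miR-200 primary transcript was far higher in all 4 transgenic libraries than in any control library. The feature miR200primary stood at 662 ± 192 CPM in transgenic hair germ against 0.786 ± 0.862 in control hair germ (log2 fold change 9.58, SE 0.51, adjusted p = 2.59e-06). In IFE it stood at 661 ± 75.8 CPM against 3.23 ± 0.848 (log2 fold change 7.73, SE 0.46, adjusted p = 5.09e-06). Its level did not differ detectably between the populations of transgenic pups (log2 fold change 0.00, adjusted p = 0.998). The transgenic effect on miR200primary was not shown to differ between populations (difference 1.84, SE 0.70, adjusted p = 0.505). The annotated hairpins Mir200a (chromosome 4, 156054896 to 156054985), Mir200b and Mir429 had 0 counts in all 8 libraries. That allows at most 0.199 to 0.522 CPM of assigned reads per library. It does not bound their expression, since reads that overlap both a hairpin and miR200primary may not have been assigned to the hairpin. Whether miR200primary covers the transgene, the endogenous transcript or both is not given in the sources used here, so its level does not separate them. Mir200c had 2 counts in IFE transgenic pup 6 and 0 in the other 7 libraries.

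In hair germ, transgenic pups had lower Cdon and Ptch1, genes of the Hedgehog pathway, lower H19 and Igf2, and higher Trps1, Tgfb2 and Vim than controls. Trps1, a transcription factor of the hair follicle, rose from 7.51 ± 0.189 to 71.0 ± 13.4 CPM (log2 fold change 3.24, SE 0.32, adjusted p = 0.00132). Tgfb2, a growth factor made by the early follicle, rose from 18.3 ± 9.20 to 210 ± 14.5 CPM (3.54, SE 0.53, adjusted p = 0.0171). Nfatc1, a transcription factor of hair follicle stem cells, rose from 90.1 ± 3.41 to 178 ± 1.01 CPM (adjusted p = 0.0459). H19, an imprinted noncoding RNA on chromosome 7 (142575529 to 142578143), fell from 3706 ± 281 to 502 ± 216 CPM (log2 fold change -2.88, adjusted p = 0.0218). Its imprinted neighbour Igf2, an insulin-like growth factor gene, fell from 275 ± 115 to 42.2 ± 28.3 CPM (-2.69, adjusted p = 0.0171). Cdon, a Hedgehog co-receptor, fell by 1.60 on the log2 scale (SE 0.23, adjusted p = 0.0165). Ptch1, the Hedgehog receptor and itself a target of the pathway, fell by 1.02 (SE 0.20, adjusted p = 0.0404). The BMP receptor gene Bmpr1b fell from 121 ± 8.03 to 43.2 ± 1.97 CPM (adjusted p = 0.0281). Other large falls were those of Slc1a3 (-2.42), a glutamate transporter, and Ror1 (-2.31), a Wnt receptor. With both libraries of pup 4 left out, 0 of these genes passed.

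Several of the largest rises in hair germ were genes of myeloid cells. Spp1, a secreted phosphoprotein, was at least 187-fold higher, with 0 counts in both control hair germ libraries and 21.7 ± 4.08 CPM in the transgenic ones. Fcgr2b, an Fc receptor, was at least 80.0-fold higher, Sfpi1, a myeloid transcription factor also known as PU.1, at least 71.0-fold, Trem2, a myeloid receptor, at least 64.2-fold, and the integrin gene Itgb2 at least 55.3-fold. Of 15 immune cell genes tested, 3 rose (Ptprc, Laptm5 and Lyz2) and 0 fell, with 8 rising and 0 falling adjusted over the list alone. The list median was 1.40 (camera adjusted p = 0.000677, and adjusted p = 0.470 with an estimated correlation). Among 11 melanocyte genes, 4 rose (Dct, Kit, Gpnmb and Pmel), 7 adjusted over the list alone, with a median of 2.93 (camera adjusted p = 1.18e-05, and adjusted p = 0.206 with an estimated correlation). Dct, an enzyme of melanin synthesis, was at 53.5 ± 11.9 CPM against 7.34 ± 5.40. Of 9 dermal papilla genes 0 passed and 6 rose adjusted over the list alone (median 2.93, camera adjusted p = 0.000337, and adjusted p = 0.225 with an estimated correlation). Of 9 Merkel cell genes 0 passed and 4 rose in the same way (median 1.51, camera adjusted p = 0.0163, and adjusted p = 0.317 with an estimated correlation). Fibroblast genes had a median of -0.38 with 0 of 10 passing (camera adjusted p = 0.157). The immune median was 0.976 without both libraries of pup 4, and 0 immune and 0 melanocyte genes passed. Without the 2 libraries rich in Rn45s 1 and 0 did.

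Among epithelial groups in hair germ, basal and cell cycle genes were lower as lists while 0 members passed singly. Basal epidermis genes had a median of -0.50, with 18 of 20 members below 0, 0 passing, and 1 rising and 2 falling adjusted over the list alone (camera adjusted p = 0.000337, and adjusted p = 0.317 with an estimated correlation). Krt15, a keratin of basal and follicle stem cells, stood at 521 ± 276 CPM against 1414 ± 303. The Hedgehog list had 2 of 14 members falling, Cdon and Ptch1, and 0 rising, against 2 falling and 1 rising adjusted over the list alone (median -0.46, camera adjusted p = 0.00589, and adjusted p = 0.317 with an estimated correlation). Lists of G2/M and mitosis genes (median -0.46, 25 of 26 members below 0, camera adjusted p = 6.33e-05), G1/S and DNA replication genes (-0.38, 0.000677), replication-dependent histone genes (-0.39, 0.0163) and actin regulators (-0.20, 0.0383) had 0 members passing, also adjusted over the list alone, and an adjusted p of 0.317 to 0.543 with an estimated correlation. Hair shaft and sheath genes had a median of 1.28 with 0 of 11 passing and 5 rising adjusted over the list alone (camera adjusted p = 0.0130, and adjusted p = 0.355 with an estimated correlation). The hair shaft median was 0.602 and the actin median -0.315 without both libraries of pup 4, and 0 Hedgehog genes passed. With an estimated correlation 0 of the 35 lists passed. The 24 lists without a camera call had adjusted p of 0.0529 to 0.957. They included the Wnt, Notch, Eda, adherens junction, desmosome, tight junction, focal adhesion, apical-basal and planar cell polarity lists, in which 0 members passed over all genes. Of 26 hair germ and placode genes 3 rose (Trps1, Tgfb2 and Nfatc1) and 0 fell, with 6 rising and 1 falling adjusted over the list alone (median 0.07).

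In hair germ 135 of 14176 genes passed, 108 higher and 27 lower in transgenic pups, and 2426 had an unadjusted p under 0.05. The count rested on the single pups. It was 199 without hair germ control pup 3, 347 without control pup 5, 16 without transgenic pup 4 and 14 without transgenic pup 6. Without both libraries of the male pup 4 it was 1, miR200primary, and without the 2 libraries rich in Rn45s it was 20. With limma-voom it was 17, with the edgeR legacy method 54 and with the DESeq2 Wald test 648. With a fit of the 4 hair germ libraries alone it was 22. Of 34 named genes that passed, 25 and 32 passed without control pups 3 and 5, and 9 and 5 without transgenic pups 4 and 6. Those passing in all 4 fits were miR200primary, Sfpi1, Spp1, Trps1 and Vim.

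**Figure D1:**
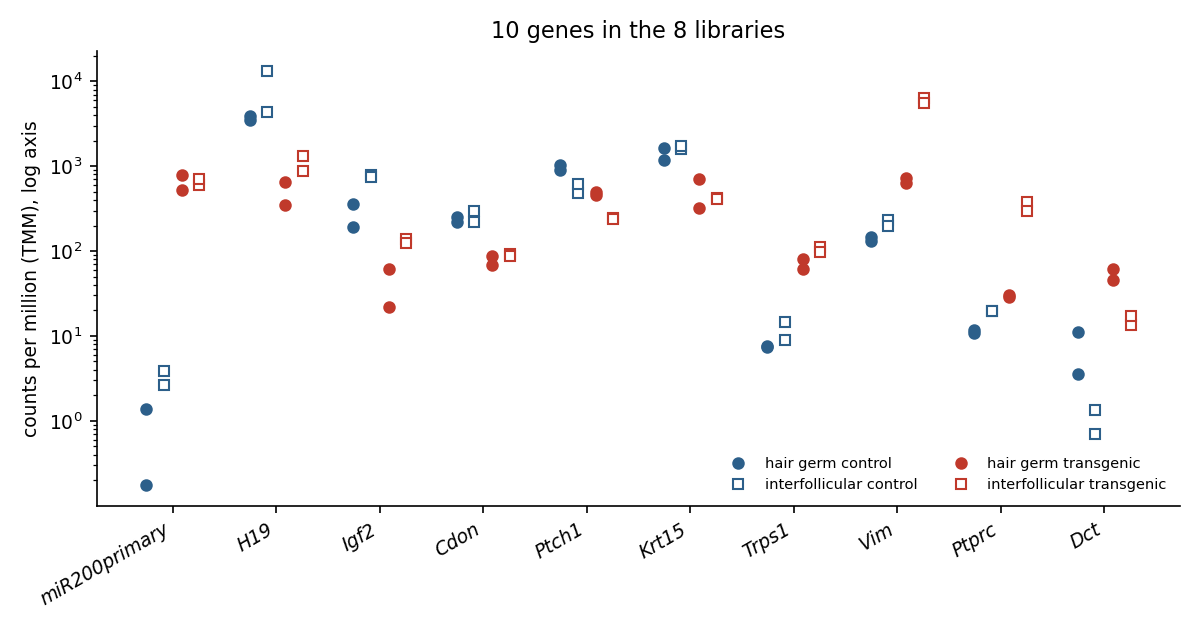
TMM-scaled CPM (vertical log axis) of 10 genes, with 1 point per library, circles for hair germ and squares for interfollicular epidermis, blue for control and red for transgenic pups. miR200primary ranges from 0.176 to 3.83 CPM in the 4 control libraries and from 526 to 797 CPM in the 4 transgenic ones.

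In IFE, transgenic pups had, as lists, lower basal keratinocyte, Hedgehog, basement membrane and DNA replication genes and much higher immune cell genes than controls. Krt15 fell from 1666 ± 117 to 417 ± 6.90 CPM (log2 fold change -2.00, SE 0.32, adjusted p = 0.00281). Egfr, the epidermal growth factor receptor, fell from 300 ± 28.2 to 110 ± 4.79 CPM (-1.44, SE 0.20, adjusted p = 0.00124). Of 20 basal epidermis genes 7 fell and 1 rose, with 15 falling and 1 rising adjusted over the list alone. The other falls were those of Itgb4 (-0.86) and Col17a1 (-0.95), parts of the hemidesmosome, Trp63 (-0.81), a transcription factor of basal epithelia, Lamb3 (-0.83) and Krt14 (-1.08). The rise was that of Ly6e (2.11). The list median was -0.80 (camera adjusted p = 2.72e-07, and adjusted p = 0.220 with an estimated correlation), against 0.03 for 22 suprabasal differentiation genes, of which Abca12 rose and 0 fell, and 0 passed adjusted over the list alone (camera adjusted p = 0.825). With library size alone as the scaling the basal median was -0.63, with 2 falling and 1 rising. Without both libraries of pup 4, or without the 2 libraries rich in Rn45s, 1 basal gene fell and 0 rose, at medians of -0.76 and -0.89.

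Hedgehog genes were lower as a list in IFE too. Of 14 members 5 fell and 0 rose, with 7 falling adjusted over the list alone. The median was -0.74 (camera adjusted p = 3.07e-05, and adjusted p = 0.220 with an estimated correlation). Cdon fell from 258 ± 56.9 to 90.7 ± 3.89 CPM (log2 fold change -1.51, SE 0.23, adjusted p = 0.00206) and Ptch1 from 551 ± 95.4 to 241 ± 4.95 CPM (-1.19, SE 0.20, adjusted p = 0.00404). Smo, the signal transducer of the pathway, and the transcription factors Gli2 (-0.95) and Gli3 (-1.05) also fell. Among 21 basement membrane and matrix genes 6 fell and 1 rose, with 12 falling and 1 rising adjusted over the list alone. The median was -0.64 (camera adjusted p = 1.19e-05, and adjusted p = 0.321 with an estimated correlation). Fras1 (-1.61) and Frem2 (-1.14), proteins that anchor the epidermis, were among the falls, and Nid2 (4.55) was the rise. Of 24 G1/S and DNA replication genes 4 fell (Mcm7, Mcm4, Rrm2 and Pole), 6 adjusted over the list alone, and all 24 lay below 0 (median -0.62, camera adjusted p = 4.65e-07, and adjusted p = 0.321 with an estimated correlation). G2/M and mitosis genes had a median of -0.58 with 1 of 26 falling, Anln, also adjusted over the list alone (camera adjusted p = 9.72e-06, and adjusted p = 0.239 with an estimated correlation). With library size alone 1 Hedgehog gene, 1 basement membrane gene and 0 G1/S genes fell, at medians of -0.60, -0.53 and -0.45, while the median of all genes moved from -0.01 to 0.15. Without both libraries of pup 4 the G1/S median was -0.352 and the G2/M median -0.383, and without the 2 libraries rich in Rn45s they were -0.375 and -0.288, with 0 genes of either list called. In these fits 0 and 1 Hedgehog genes fell and 0 basement membrane genes fell.

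Several lists of junction and polarity genes, which the series title names as a theme, were lower in IFE. Among 15 desmosome genes 2 fell, Perp (-1.09) and Dsg3 (-0.80), and 0 rose, with 7 falling and 1 rising adjusted over the list alone (median -0.64, camera adjusted p = 0.00116, and adjusted p = 0.239 with an estimated correlation). Among 21 planar cell polarity genes 2 fell, Celsr1 (-1.20), an atypical cadherin of the core pathway, and Ptk7 (-0.85), and 0 rose, the same counts adjusted over the list alone (median -0.41, camera adjusted p = 0.0177, and adjusted p = 0.518 with an estimated correlation). Adherens junction genes (median -0.37, 0 of 20 passing, camera adjusted p = 0.00269, and adjusted p = 0.360 with an estimated correlation) and apical-basal polarity genes (median -0.43, 0 of 23 passing, camera adjusted p = 0.00251, and adjusted p = 0.241 with an estimated correlation) were lower as lists only, also adjusted over the list alone. Among 32 focal adhesion and hemidesmosome genes 4 rose (Tns3, Pxn, Itgb5 and Itgav) and 4 fell (Itga2, Col17a1, Itgb4 and Ptk2), 4 and 6 adjusted over the list alone (median -0.23, camera adjusted p = 0.226). The 15 tight junction and 38 actin genes had medians of -0.01 and -0.04, which turned to 0.06 and 0.09 with library size alone and were -0.57 and -0.14 without the 2 libraries rich in Rn45s, with 0 members passing in the first and Fhod1 rising in the second, the same adjusted over the list alone. With library size alone 0 desmosome and 0 planar polarity genes fell, 3 focal adhesion genes rose and 0 fell, and the planar polarity, adherens junction and focal adhesion medians were -0.248, -0.222 and -0.0469. Without both libraries of pup 4, or without the libraries rich in Rn45s, 0 genes of these 7 lists were called, and without the latter the planar polarity median was -0.17. Cdh3, which encodes the P-cadherin used for sorting, had log2 fold changes of -0.20 in IFE (adjusted p = 0.781) and 0.34 in hair germ (adjusted p = 0.480). Itga6, the alpha6 integrin gene, had -0.78 (adjusted p = 0.0598) and -0.33.

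Markers of immune cells and melanocytes rose in the same IFE libraries. Of 15 immune cell genes 14 rose and 0 fell, 15 adjusted over the list alone, with a median of 4.18 (camera adjusted p = 4.96e-14, and adjusted p = 0.220 with an estimated correlation). Ptprc, the leukocyte antigen CD45, rose from 19.8 ± 0.111 to 337 ± 58.4 CPM (log2 fold change 4.09, SE 0.25, adjusted p = 7.78e-06). Spp1 rose from 1.28 ± 1.56 to 267 ± 46.3 CPM. The rises of the myeloid receptor genes Ptafr and Clec7a had ratios of 239 (interval 42.6 to 9486) and 157 (43.0 to 1298), since the controls held few counts. Of 11 melanocyte genes 5 rose (Gpnmb, Mitf, Dct, Kit and Pmel), 6 adjusted over the list alone, with a fitted median of 5.04 and 3.77 with members at 0 set to their bound (camera adjusted p = 1.61e-06, and adjusted p = 0.190 with an estimated correlation). Dermal papilla genes had a median of 2.58, or 1.69 at the bound, with 0 of 9 passing, also adjusted over the list alone (camera adjusted p = 0.0137, and adjusted p = 0.239 with an estimated correlation). Fibroblast genes had a median of -0.89, with Postn falling and 3 falling adjusted over the list alone (camera adjusted p = 0.0108, and adjusted p = 0.321 with an estimated correlation). Endothelial genes (2.96, or 2.35 at the bound), Merkel cell genes (1.14, Krt18 rising), skeletal muscle genes (1.31), Schwann genes (0.16) and mural cell genes (-0.30) had no camera call. Without both libraries of pup 4, or without the libraries rich in Rn45s, 11 and 12 immune genes and 2 and 1 melanocyte genes rose, and the dermal papilla medians were 1.35 and 1.19.

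Mesenchymal genes and textbook miR-200 targets did not move in 1 direction. Vim, an intermediate filament of mesenchymal and immune cells, rose from 213 ± 24.6 to 5953 ± 498 CPM in IFE (log2 fold change 4.80, SE 0.25, adjusted p = 4.75e-06) and from 139 ± 10.2 to 683 ± 64.9 CPM in hair germ (2.30, SE 0.23, adjusted p = 0.00132). Of 13 mesenchymal genes in IFE 2 rose, Vim and Zeb2, and 1 fell, Snai2 (-1.08), 3 and 2 adjusted over the list alone, with a median of -0.12 that turned to 0.02 with library size alone. Zeb2, a repressor of epithelial genes and a textbook target of the family, rose by 4.90 on the log2 scale in IFE (SE 0.54, adjusted p = 0.000299), in the libraries where immune cell genes had a median of 4.18, and stood at 1.46 in hair germ (adjusted p = 0.166). Its relative Zeb1 stood at 2.53 in IFE (adjusted p = 0.0944) and 2.13 in hair germ (adjusted p = 0.383). Of 25 textbook targets 3 rose in IFE (Zeb2, Lrp1 and Fhod1) and 0 fell, 5 and 0 adjusted over the list alone. The median was -0.11, or -0.15 with members at 0 at their bound, and turned to 0.08 with library size alone (camera adjusted p = 0.899). In hair germ 0 of the 25 passed over all genes, and 3 rose and 5 fell adjusted over the list alone (median -0.13, camera adjusted p = 0.241). There 9 of the 25 lay above 0. In the fit without the other cell type and myeloid lists, chosen after the data were seen, 22 targets were left. Of these 6 lay above 0 and 0 passed, at a median of -0.275.

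Among the remaining lists in IFE, 4 of 26 hair germ and placode genes rose and 0 fell, with 5 rising and 2 falling adjusted over the list alone. They were Trps1 (3.18), Nfatc1 (1.63), Cxcr4 (2.60), a chemokine receptor also found on leukocytes, and Runx1 (1.30), and the median was 0.41 (camera adjusted p = 0.236). Of the 26 genes 2 rose without both libraries of pup 4 (median 0.237) and 2 without the libraries rich in Rn45s. Wnt genes had a median of -0.52 with Wls, needed for Wnt secretion, falling and 5 of 27 falling adjusted over the list alone (camera adjusted p = 0.0137, and adjusted p = 0.360 with an estimated correlation). The Wnt median was -0.257 without both libraries of pup 4 and -0.294 without the libraries rich in Rn45s, with 0 genes called in both. Of 24 Bmp and Tgf-beta genes 4 rose (Tgfbr1, Id2, Tgfb1 and Smad7) and 1 fell (Bmpr1b), with 5 and 7 adjusted over the list alone. The list median was -0.25. It was -0.0941 with library size alone, where 5 of these genes rose, 0 fell, and 0 Wnt and 0 Notch genes fell, at medians of -0.323 and -0.276. With both libraries of pup 4 left out 1 Bmp and Tgf-beta gene was called, and 2 without the libraries rich in Rn45s. Tgfbr1 stood at 2.30 in IFE and 0.42 in hair germ, and its effect, like that of Ptprc, differed between the populations (difference -1.87). Immune cell genes rose in the same IFE libraries. Whether the rises in this and the other lists came from keratinocytes or from immune cells was not tested. Replication-dependent histone genes had a median of -0.40 with 0 of 13 passing (camera adjusted p = 0.0460, and adjusted p = 0.279 with an estimated correlation). Lists without a camera call, with adjusted p of 0.113 to 0.9996, also included Notch genes (1 rose, Rbpj, and 2 fell, Dll1 and Lfng), Eda genes (Cxcl16 rose and Tnfrsf19 fell), hair shaft genes (median 0.10, and 0.325 without both libraries of pup 4 or 0.921 with 1 rising without the libraries rich in Rn45s), housekeeping genes (Gusb and B2m rose), p53 targets (Perp fell), immediate early genes (Dnajb1 fell), and ribosomal protein genes (median -0.06, turning to 0.10 with library size alone).

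In IFE 899 genes passed, 707 higher (78.6%) and 192 lower in transgenic pups. H19 fell from 8763 ± 6155 to 1100 ± 296 CPM (-2.99, adjusted p = 0.00274) and Igf2 from 766 ± 36.4 to 132 ± 11.2 CPM (-2.54, adjusted p = 0.00247). With library size alone 909 passed, 867 higher (95.4%) and 42 lower. The count was 537 without IFE control pup 3, 303 without control pup 5, 344 without transgenic pup 4 and 500 without transgenic pup 6. It was 207 (203 higher and 4 lower) without both libraries of pup 4 and 195 without the 2 libraries rich in Rn45s. Of 63 named genes that passed, 41 and 32 passed without control pups 3 and 5, and 31 and 38 without transgenic pups 4 and 6. The 24 that passed in all 4 fits included Cdon, Egfr, Fras1, H19, Igf2, Krt15, Nfatc1, Ptprc, Tgfbr1, Trps1, Vim and Zeb2, and did not include Ptch1.

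**Figure D2:**
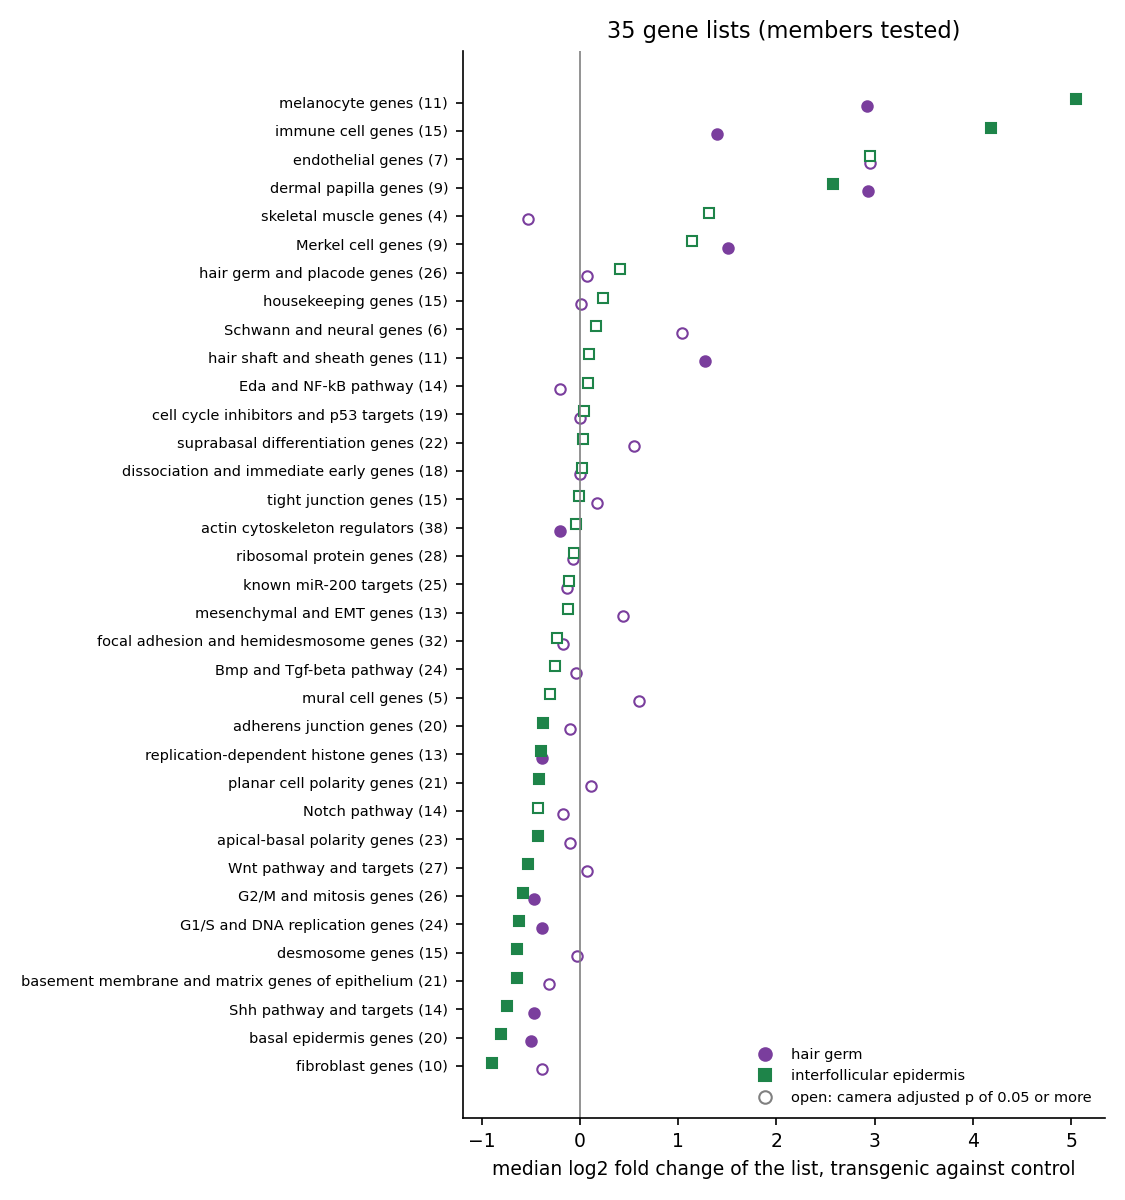
Median log2 fold change of each of the 35 gene lists (horizontal axis, members tested in brackets) for transgenic against control pups, circles for hair germ and squares for interfollicular epidermis, filled where camera with the preset correlation called the list. In interfollicular epidermis the immune cell list lies at 4.18 and the basal epidermis list at -0.80.

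The transgenic effects in the 2 populations shared more genes than independent calls would give. Of the genes called in both, 67 were higher and 18 lower in both populations, against 5.39 and 0.366 from the product of the call rates, and 0 went opposite ways, against 2.81. Among the 67 were miR200primary and Trps1, and also the immune cell genes Ptprc, Laptm5 and Lyz2. They included the myeloid genes Fcgr2b, Sfpi1 and Trem2 and the melanocyte genes Dct, Kit, Gpnmb and Pmel. The shared rises therefore do not describe keratinocyte genes alone. The 18 lower in both were H19, Ror1, Igf2, Slc1a3, C1qtnf1, H60c, Akap2, Oat, Wnt7a, Cxcr7, Adamts14, Cdon, Chst15, Frmd6, Ptch1, Crybg3, Bmpr1b and Mef2a. At an unadjusted p under 0.05, 496 genes were higher and 299 lower in both, and 18 went opposite ways. Across the 14176 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.356 and a Spearman rho of 0.392. The r was 0.538 over the 7365 more abundant genes. The other 2 ways to pair the 4 pups gave 0 calls in either population and an r of 0.0883 and 0.0625, or 0.341 and 0.331 over the more abundant genes. Each arm of those splits held 1 transgenic and 1 control pup, so the transgenic effect added to the spread within groups. Few or no calls were bound to follow, and the 0 is no benchmark for the real split. With edgeR those splits had 760 and 730 genes at an unadjusted p under 0.05 in hair germ and 110 and 26 in IFE, and no other tool was run on them. Both populations came from the same pups, so a difference between pups moves both.

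Genes with a miR-200 seed match in the 3' UTR had a lower mean change in transgenic pups than genes without. Their mean log2 fold change was above 0, at 0.26 in hair germ and 0.22 in IFE, against 0.43 in both without a site. Their medians were -0.05 and -0.12, against 0.08 and 0.03. The mean log2 fold change was lower by a difference of -0.17 in hair germ and -0.20 in IFE, between 4220 genes with a site and 9110 without (permutation p = 1e-05 in both, the smallest it can give). Against a background matched on UTR length and abundance the differences were -0.11 (permutation p = 0.00047) and -0.15 (p = 1e-05). With the 8-base match they were -0.27 and -0.28. Among the 419 other words of the same bases, 3 had a lower value than CAGTATT, the site of miR-200b and miR-429, in either population, while 22 and 27 were lower than CAGTGTT, the site of miR-200a. Over the genes with a mean log2 CPM of at least 4, a subset chosen after the data were seen, 0 words were lower than CAGTATT in both populations, and 3 and 13 were lower than CAGTGTT. Without transgenic pup 4 the hair germ difference was -0.10 (permutation p = 0.0164) and without transgenic pup 6 it was -0.10 (p = 0.00408), against -0.29 and -0.26 without control pups 3 and 5.

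Genes that fell held sites more often than the rest, in counts not matched on UTR length or abundance. Sites were more common among abundant genes: at a mean log2 CPM of at least 4, 2742 genes held one and 4828 did not. Part of the excess may come from that, and the exact tests treat genes as independent, which they are not. In hair germ 16 of 26 called lower genes with a UTR had a site (61.5%, against 31.6% of genes not called, Fisher's exact p = 0.00226). In IFE 97 of 189 did (51.3% against 31.5%, Fisher's exact p = 2.37e-08). Called higher genes had shares of 31.4% (exact p = 1.0) and 28.7% (exact p = 0.121). Of the 18 genes lower in both populations, 13 held a site, 4 had none (Adamts14, C1qtnf1, Cxcr7 and Wnt7a), and H19, a noncoding RNA, was not searched. Cdon has a miR-200b site on chromosome 9 at 35506002 to 35506008 (CATTTGTCAGTATTCCCTTAC) and a miR-200a site at 35504839 to 35504845. Ptch1 has 2 miR-200a sites on chromosome 13, at 63517320 to 63517326 (GAAAATCCAGTGTTTTAAGAT) and 63508494 to 63508500. Bmpr1b has a miR-200b site on chromosome 3 at 141839267 to 141839273 (ATATGACCAGTATTCCTTAGA) and a miR-200a site at 141839081 to 141839087. Akap2, which encodes an anchoring protein of protein kinase A, has 6 sites in 4091 bases of UTR.

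**Figure D3:**
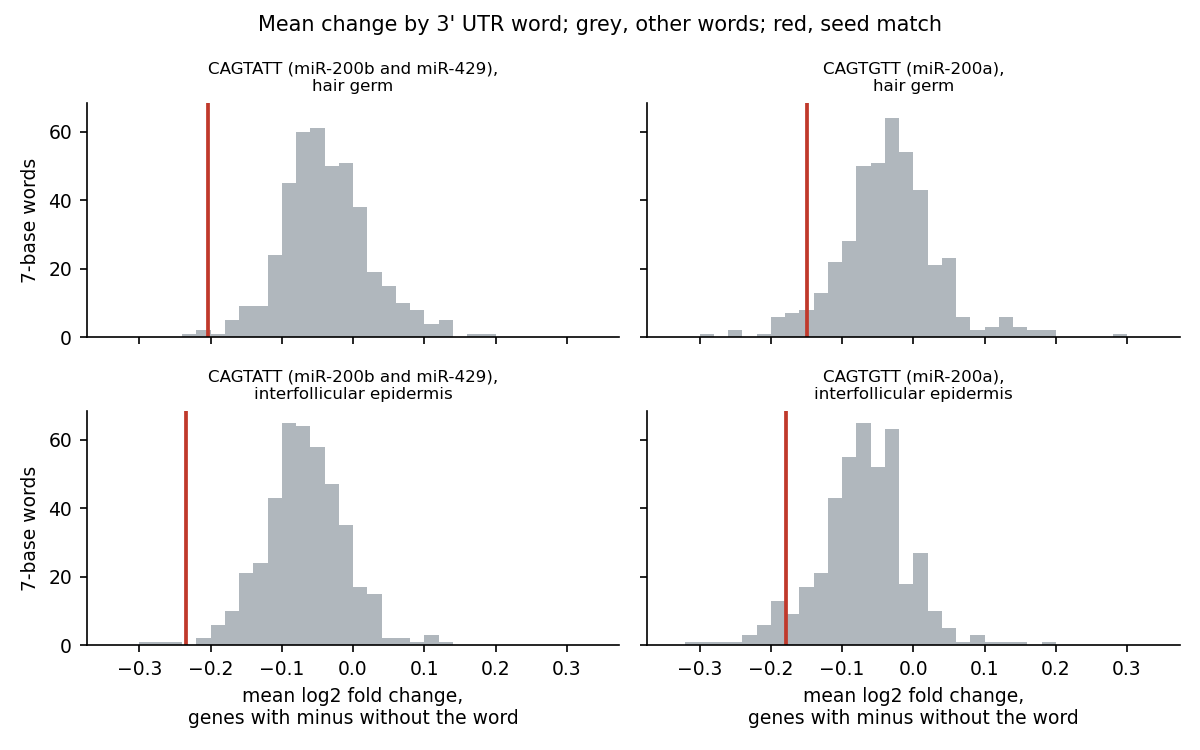
Number of 7-base words (vertical axis, grey bars, 419 other words per panel) by the difference in mean log2 fold change between genes with and without the word in their 3' UTR (horizontal axis), over all genes with a 3' UTR, with CAGTATT or CAGTGTT as a red line, in each population. CAGTATT lies at -0.20 in hair germ and -0.23 in interfollicular epidermis.

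In control pups, hair germ cells had higher hair germ and Hedgehog genes than IFE cells, and lower suprabasal and immune cell genes, as lists. Of 26 hair germ and placode genes 4 rose adjusted over the list alone, and 0 passed over all genes. These were Edar, the ectodysplasin receptor gene, Lhx2 and Foxi3, transcription factors of the placode, and Ctgf. The list median was 0.58 (camera adjusted p = 4.23e-05, and adjusted p = 0.196 with an estimated correlation). Of 14 Hedgehog genes 7 rose adjusted over the list alone and 0 over all genes (median 0.50, camera adjusted p = 5.98e-05, and adjusted p = 0.248 with an estimated correlation). Camera also called suprabasal (median -0.81, adjusted p = 0.0170), desmosome (-0.36, 0.0416), G2/M (0.22, 0.0284), Merkel cell (2.06, or 1.86 with members at 0 at their bound, 0.000441), melanocyte (1.10, or 1.74 at the bound, 0.0284) and immune cell lists (-0.72, 0.0274). With an estimated correlation their adjusted p was 0.224 to 0.719. Without the 2 libraries rich in Rn45s the medians were -0.405 for suprabasal, 3.94 for Merkel cell, 0.553 for melanocyte and -0.185 for immune cell genes. The ribosomal protein list had a median of -0.29 that turned to 0.04 with library size alone (camera adjusted p = 0.0439, and adjusted p = 0.323 with an estimated correlation). With the pup as a block its call ended (adjusted p = 0.0613) while the other 8 held. Basal epidermis genes had a median of -0.26, turning to 0.06 with library size alone, where the median of all genes moved to 0.26. Cdh3 itself stood at 394 ± 59.3 CPM in hair germ and 339 ± 65.6 in IFE (log2 fold change 0.22, SE 0.23, adjusted p = 0.804), so the surface protein used to separate the populations had no detectable difference in RNA.

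With edgeR 1 gene passed between the populations of control pups, the predicted gene Gm6537, named after its value was seen (log2 fold change 6.21, SE 0.71, adjusted p = 0.00886), with 490 and 670 counts in hair germ and 6 and 4 in IFE. In all, 1200 genes had an unadjusted p under 0.05. DESeq2 called 152, limma-voom 0, the edgeR legacy method 6 and the fit with the pup as a block 7. The count was 123 without hair germ control pup 5 and 0 without IFE control pup 3, and without IFE control pup 5 it was 1, a different gene.

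In transgenic pups the same comparison gave, as lists, higher Hedgehog, Wnt and planar polarity genes in hair germ than in IFE and lower immune cell genes. Of 14 Hedgehog genes 7 were called higher and 0 lower, 8 adjusted over the list alone. Among them were Shh, the signal itself (log2 fold change 3.16), and Gli1 (1.36), a transcription factor and target of the pathway. The median was 0.93 (camera adjusted p = 1.09e-05, and adjusted p = 0.238 with an estimated correlation). Of 26 hair germ and placode genes 4 were called higher (Ctgf, Lhx2, Shh and Edar) and 1 lower (Cxcr4), 9 and 2 adjusted over the list alone, with a median of 0.69 (camera adjusted p = 0.0102, and adjusted p = 0.238 with an estimated correlation). Planar cell polarity genes were positive in 21 of 21, with Fat1, Fat4 and Ptk7 called and 5 adjusted over the list alone (median 0.58, camera adjusted p = 6.42e-05, and adjusted p = 0.393 with an estimated correlation). Wnt genes were positive in 25 of 27, with Rnf43 called and 6 adjusted over the list alone (median 0.80, camera adjusted p = 1.54e-05, and adjusted p = 0.252 with an estimated correlation). Basement membrane genes (Frem1, Frem2, Col7a1 and Col4a2 higher, Nid2 lower, 9 and 1 adjusted over the list alone, median 0.59, camera adjusted p = 0.000476, and adjusted p = 0.448 with an estimated correlation), hair shaft genes (Gata3 and Krt17 higher, 4 higher and 1 lower adjusted over the list alone, median 1.06, camera adjusted p = 0.0279, and adjusted p = 0.393 with an estimated correlation) and Merkel cell genes (Rab3c higher, 6 adjusted over the list alone, median 3.07, camera adjusted p = 4.35e-05, and adjusted p = 0.238 with an estimated correlation) were called by camera too. So were dermal papilla (1.22), G1/S (0.45), G2/M (0.31), apical-basal polarity (0.42), adherens junction (0.21), immediate early (-0.27) and housekeeping lists (-0.32), with an adjusted p of 0.00218 to 0.0350, and of 0.252 to 0.628 with an estimated correlation. Of 15 immune cell genes 14 were lower and 0 higher in hair germ than in IFE, also adjusted over the list alone (median -3.50, camera adjusted p = 1.14e-11, and adjusted p = 0.238 with an estimated correlation). With an estimated correlation 0 of the 35 lists passed, and with the pup as a block 15 lists were called, the fibroblast list (adjusted p = 0.0307) in place of the housekeeping list (0.0686). The medians were 0.406 for hair shaft, 0.106 for G2/M and 2.05 for dermal papilla genes without both libraries of pup 4, and 0.166 for G1/S genes without the libraries rich in Rn45s.

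Between the populations of transgenic pups 655 genes passed, 124 higher (18.9%) and 531 lower in hair germ. The transcription factor genes Pou3f3 (log2 fold change 6.63) and Olig2 (6.35) had the largest rises, and the leukocyte genes Evi2b (at least 182-fold lower) and P2ry12 (ratio 0.00415, interval 0.000502 to 0.0151) were among the largest falls. With the pup as a block the count was 1018. It was 0 without both libraries of pup 4 and 192 without the 2 libraries rich in Rn45s. It was 237 without hair germ transgenic pup 4, 47 without hair germ transgenic pup 6, 211 without IFE transgenic pup 4 and 368 without IFE transgenic pup 6. With library size alone it was 666, 179 higher and 487 lower. Cdh3 stood at 499 ± 109 CPM in hair germ and 295 ± 19.7 in IFE (log2 fold change 0.76, SE 0.23, adjusted p = 0.0889).

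The transgenic effect itself differed between the populations for 19 genes, each with a lower effect in hair germ. They included Dock2 (difference -3.75, SE 0.59, adjusted p = 0.0479), Lsp1 (-3.43), Akna (-3.33) and Ctsz (-3.18), genes of leukocytes and lysosomes. Ptprc (-2.69) and Vim (-2.51) were among them too. The immune cell list had a difference of -2.85 (camera adjusted p = 1.12e-08, and adjusted p = 0.706 with an estimated correlation), with Ptprc alone of 15 genes called over all genes and 10 adjusted over the list alone. The Wnt list had a difference of 0.43, with 0 of 27 called over all genes and 1 adjusted over the list alone (camera adjusted p = 0.0363, and adjusted p = 0.706 with an estimated correlation). The other 33 lists had camera adjusted p of 0.0576 to 0.957, so no difference of effects between the populations was shown for them. In all, 1149 genes had an unadjusted p under 0.05. The count was 48 and 192 without hair germ control pups 3 and 5, 2 and 3 without IFE control pups 3 and 5, and 0 without any 1 of the 4 transgenic libraries or without the 2 libraries rich in Rn45s. DESeq2 called 177 genes, limma-voom 1, the edgeR legacy method 2, and the fit with the pup as a block 86. Leaving out ribosomal RNA and the 10 most abundant genes gave 1, and leaving out the other cell type and myeloid lists gave 0.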

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

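The tests of myeloid genes, of the difference between suprabasal and basal medians, of basal genes without the libraries rich in Rn45s or without pup 4, of sequencing depth, of genes detected without the cell type and myeloid lists, and of reads outside genes were chosen after the data were seen, while that of TMM scaling was set before.

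A test of the difference between populations picked out 19 genes whose transgenic effect was lower in hair germ than in IFE, among them Dock2 (-3.75), Lsp1 (-3.43), Akna (-3.33) and Ctsz (-3.18). The same contrast picked out the Wnt list (median difference 0.431) and the immune cell list (-2.85) with camera, and with an estimated correlation both had an adjusted p of 0.706. Mir141, which no contrast used, had 15 counts in hair germ of transgenic pup 4, 0 in hair germ of pup 6, and 4 and 1 in IFE of pups 4 and 6, against 0 in all 4 control libraries.

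Myeloid genes were higher in transgenic libraries, by far the most in IFE, where Csf1r stood at 969 and 707 CPM, Mrc1 at 767 and 596, Ptprc at 378 and 296 and Lyz2 at 339 and 237 in pups 4 and 6. A lower share of keratinocytes would raise all other cell types alike. In IFE, marker genes at 1 to 10 CPM in controls had medians of 4.52 (immune), 3.77 (melanocyte), -0.0973 (Schwann), -0.448 (fibroblast) and -0.573 (mural, permutation p = 0.0005 over the lists). These values argue only against a uniform rise of those markers, since each list but the immune one held 3 members. The window left out the dermal papilla (2.58), endothelial (2.96), Merkel (1.14) and skeletal muscle lists (1.31), all with fitted medians above 0. The permutation also treats genes as independent, so the explanation is not decided in IFE. In hair germ it cannot be told apart from other causes, since melanocyte (2.91), Merkel (1.5) and endothelial genes (1) lay above 0 beside the immune genes (1.41) and only 3 skeletal muscle genes (0.38) lay apart (permutation p = 0.0243). First versions of the marker test, with the fibroblast list median of -0.894 in IFE and a looser bound, were replaced after they were seen. In IFE the rise was also seen in the female pup 6, with an immune list mean of 6.814 log2 CPM. The mean was 7.049 in pup 4, and 3.134 and 2.264 in control pups 3 and 5. This argues against the male pup as the whole cause in IFE, but rests on 1 transgenic library. The male pup cannot be told apart in hair germ, where 1 transgenic library was left too and the list median went from 1.40 to 0.976. RNA of myeloid cells from 1 source may contribute: for the 13 of 15 genes with an excess in both populations, the log2 ratio of the excess in hair germ to that in IFE had a median of -3.89 and an interquartile span of 0.7, while the sort for K14RFP and alpha6 integrin should have removed such cells. Of the 15 genes 11 were at 1 CPM or more in every control library. On another of the lists fixed beforehand there are 0, not counting the myeloid list added later. Whether the transgene brought such cells, changed their carry-over or acted otherwise was not tested.

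Basal epidermis genes were lower in transgenic IFE, with a median of -0.799 against 0.034 for suprabasal genes. Dilution of keratinocyte RNA by RNA of other cells should lower both lists alike if both came from the same cells. Their medians differed by 0.833 (permutation p = 0.00098). The sort took cells high for alpha6 integrin, so suprabasal RNA may depend on the gate, and the permutation treats genes as independent. Dilution is therefore not decided by this difference. Scaling is argued against as the whole cause by a basal median of -0.63 with library size alone, although only 2 members then fell, and the libraries rich in Rn45s by a median of -0.888 without them and the male pup by -0.759 without pup 4, although only 1 of 20 then passed as lower in each, with fewer samples. An effect of the transgene on basal cells stays open as a hypothesis, beside dilution, the different genotypes of the control pups and a shift in which cells the gate took.

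More genes were detected in transgenic libraries, 14791 to 16344 against 13446 to 14378 in controls. Depth is argued against by a gap of 276 genes between the lowest transgenic and the highest control library after thinning to 5000000 counts without Rn45s. With the lists of other cell types and the added myeloid list left out the gap was 284 genes. That removed only 376 names, Rn45s included, and not the other genes of such cells, so RNA of those cell types is not decided. Genomic DNA or intronic reads cannot be told apart from the groups, since every transgenic library had a larger share of reads outside genes in 1 population, hair germ (58.9% and 58.4% against 51.0% and 55.7%), and not in IFE (64.4% and 52.2% against 63.3% and 52.9%), and a first version of that test, the mean difference, was replaced after it was seen. Cell types outside the lists and the transgene itself were not tested.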

How the results depend on the processing

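The fits without the added myeloid list, without the libraries rich in Rn45s, without the transgenic IFE libraries and without the male pup 4, and the seed tests on abundant genes or without cell type lists, were chosen after the data were seen. Counts are in the order hair germ transgenic effect, IFE transgenic effect, population difference in controls, population difference in transgenics, and difference of effects, where the reported counts are 135, 899, 1, 655 and 19. The cause of a change was not tested unless stated.

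DESeq2 size factors moved the control population count to 2. Library size alone gave 316 in hair germ, 29 in controls and 97 for the difference of effects, and it moved the median of all genes to 0.149 in IFE, 0.264 between control populations and 0.199 between transgenic ones, so changes there count relative to that shift. No filter gave 3 in controls and 45 for the difference of effects, and the filter of 5 CPM gave 6 in controls. The DESeq2 Wald test gave 648 in hair germ, 152 in controls and 177 for the difference of effects. The edgeR legacy method, the default of its version, gave 54, 541, 6, 336 and 2, and limma-voom 17, 661, 0, 558 and 1. Fitting only the 4 libraries of a contrast gave 22 in hair germ, 1277 in IFE, 1 in controls and 1385 in transgenics. Such a fit has fewer residual degrees of freedom and its own estimate of the spread. Libraries of 1 group were less alike in hair germ (r of 0.872 and 0.878) than in IFE (0.935 and 0.969), while the main fit shares 1 spread over all groups. Without ribosomal RNA and the 10 most abundant genes the counts were 0 in controls and 1 for the difference of effects, and without the other cell type lists 2 in controls. The pup as a fixed block gave 7, 1018 and 86 in the last 3 contrasts, and as a random block in limma-voom 26 in hair germ.

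Without the other cell type and myeloid lists the counts were 57, 629, 2, 401 and 0. Without the 2 libraries rich in Rn45s they were 20, 195, 0, 192 and 0, and without the male pup 1, 207, 1, 0 and 0, with fewer samples in both. Without both transgenic IFE libraries hair germ had 22. Leaving out 1 library at a time gave 14 to 347 in hair germ, 303 to 537 in IFE, 0 to 123 in controls, 47 to 368 in transgenics and 0 to 192 for the difference of effects. In those fits the lone library of a group was assumed to vary like the other groups.

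Camera called 11, 15, 9, 15 and 2 lists. With an estimated correlation it called 0 in all 5 contrasts. The directional fry test called 5, 10, 4, 9 and 0, and its mixed test 21, 24, 4, 23 and 7. Genes called in both populations in the same direction went from 85 to 795 at an unadjusted p under 0.05. The seed differences kept their direction and stayed past the threshold in every setting run, from -0.288 to -0.0953 in hair germ and -0.280 to -0.153 in IFE.

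For the 167 results on single named genes, other settings left 1832 values on the same side of the threshold, 428 weaker, 43 stronger and 11 reversed, and leaving out 1 library left 418, 269, 10 and 7. Each reversal was of a value near 0 that had not passed. For miR200primary between transgenic populations these were -0.00492 with DESeq2 size factors, -0.0405 with no filter, -0.0234 with the filter of 5 CPM, -0.00432 with the Wald test, -0.0411 with limma-voom, -0.018 without ribosomal and abundant genes, -0.0232 with the pup as a block, -0.0143 without the cell type and myeloid lists, -0.136 without the libraries rich in Rn45s, -0.364 without hair germ pup 6 and -0.124 without IFE pup 4, the fits without 1 library ranging from -0.364 to 0.223. In the same contrast Itga6 turned to 0.0821 and Krt14 to 0.117 with library size alone, Itga6 to 0.0213 without IFE pup 6 (lowest of such fits -0.246) and Krt14 to 0.0399 without hair germ pup 6 (lowest -0.243). Zeb2 between control populations turned to -0.151 without hair germ pup 3 and -0.625 without IFE pup 5 (highest 1.57), and Cdh3 in IFE to 0.0173 without IFE control pup 5 (lowest -0.323).

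In simulated data of this size 11.9% to 14.9% of genes changed by 1 on the log2 scale were found in the first 4 contrasts and 2.99% for the difference of effects.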

Other observations

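The test of imprinted growth genes, the imprinted and myeloid lists, and the fits without the male pup or the libraries rich in Rn45s were chosen after the results were seen.

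Other members of the imprinted growth gene group moved in part with H19 and Igf2. In IFE Peg3 (log2 fold change -1.30), a transcription factor gene expressed from the paternal copy, and Slc38a4 (-0.76), an amino acid transporter gene, fell, while Gatm, an enzyme of creatine synthesis, rose in both populations. With the other cell type and myeloid lists left out, 13 imprinted genes were tested in hair germ and 0 rose, so the rise of Gatm was no longer among the calls. The list of 16 genes had 15 tested, with a median of -0.76 in IFE and -0.30 in hair germ, where without the male pup it was 0.02 with 0 calls, so the direction did not hold. Lower expression of imprinted growth genes as a group is a candidate explanation for the falls of H19 and Igf2, and it was tested on the 13 other members against 10000 random lists. Their median was -0.695 in IFE (percentile 0.01) and -0.157 in hair germ (percentile 20.3), so the test leaves the explanation undecided in hair germ.

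The added myeloid list had 236 tested genes, of which 183 rose and 0 fell in IFE (25.9% of all rises) and 31 rose and 0 fell in hair germ (28.7% of all rises). Without the libraries rich in Rn45s 99 of 238 rose in IFE and 3 in hair germ, and without the male pup 95 and 0. Between the populations of transgenic pups 160 were lower in hair germ and 0 higher, and of the 19 genes whose transgenic effect differed, 11 were on that list.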
